A study of Mus musculus with 4 samples.

How the data were processed

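Gene-level read counts from 4 RNA-seq libraries of mouse T cells were analysed, each library a biological replicate of the only group the labels give. Replicate numbers came from the labels, and the number in each file header equalled that of its label in 4 of 4 cases. Per the file headers, the deposited values are raw counts of read pairs per gene, made with featureCounts 1.4.6-p4 over exons of the GENCODE M13 annotation, with both ends required to map and strand option 2. The headers name alignments made with STAR; the assembly is mm10 per the labels. The STAR version, trimming, and the handling of reads that map to several places or overlap several genes are not given in the sources used here. The headers also carry each gene's summed exon length. The labels call the assay total RNA-seq, while the linked library protocol is named for polyadenylated RNA. The labels record the sex of the animals as not collected.

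Each file lists 50600 genes. Symbols were matched for 50376 of them (99.6%); the 224 without one held at most 0.0092% of a library's counts. Biotypes, transcripts and symbols came from GENCODE M21. The design had assumed TPM, but the files hold counts. Levels were therefore tested in CPM, as the design provided for count files, and TPM was computed from the counts and the gene lengths for the gene pairs and the naming rule. CPM does not correct for gene length, so it favours long genes in comparisons between genes.

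A gene's mean log2(CPM + 0.1) was tested against 1 CPM with limma 3.58.1 (intercept only, empirical Bayes with trend, one-sided in each direction, Benjamini-Hochberg adjusted p below 0.05), over the 23365 genes with at least 1 count in any library. Gene pairs were tested with limma on the difference of log2(TPM + 0.1) within each library, two-sided, adjusted over 40 pairs. The pseudocount pulls such a ratio toward 0 where a gene lies near or below it. Genes at 0 counts were given a floor of 3 counts per library. Differences between replicates used edgeR 4.0.16 with TMM scaling (factors 0.9958 to 1.002) on the 13279 genes that passed filterByExpr. Variable genes came from the goodness-of-fit test at the trended dispersion, and each library against the other 3 and each split of the libraries into 2 and 2 from the quasi-likelihood F test, with Benjamini-Hochberg adjustment. The lone library in such a test is assumed to vary like the other 3. Coherence of a list was the mean pairwise correlation of its members' log2 CPM deviations over the libraries, against 10000 random lists matched in 20 bins of abundance (permutation test, smallest p 1e-04). Segment shares carry Wilson 95% intervals. DESeq2 1.42.0 was an alternative. Other tools were R 4.3.3, python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1, matplotlib 3.10.9 and blastn 2.17.0+.

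The tests, 28 gene lists, 8 lists of markers of other cell types, the gene pairs and the rule for naming genes were made before the data were examined, except where stated. The rule allows both members of each pair, the 4 members of each list highest in TPM among those above the threshold, any member of the helper lineage, cytokine, sex-linked and marker lists, the 20 most abundant protein-coding genes, the 20 most variable genes, up to 3 genes in each direction per replicate, the 5 most used Trbv and Trav segments, and genes used in a test of an explanation. Genes called in a split, genes beyond that limit and the members completing a count of 5 or fewer were chosen after their values were seen. Lists that the labelled cells could hold cover T cell identity, CD8 and cytotoxic, gamma-delta, naive, activation, Th1, Th2, Th17, regulatory, follicular helper, cytokine, homing, inhibitory receptor and cytokine receptor genes. The others cover the cell cycle, metabolism, stress, interferon, hypoxia, p53, noncoding and sex-linked genes.

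The tests of replicates, variable genes and coherence were tried on simulated counts drawn from the real means and library sizes. The level test was tried on set levels with the real library sizes and a fixed dispersion. With 200 of 13279 genes changed, the test of 1 library against 3 recovered 65.7%, 79.1% and 93.9% of changes of 1.5-fold, 2-fold and 4-fold and called 7 unchanged genes. The test of 2 libraries against 2 recovered 64.2%, 80.6% and 93.9% and called 11 unchanged genes. The test of variable genes recovered 53% and 82% of genes with an added log2 SD of 0.5 and 1, with 2 others called. The level test placed 100% of genes at 0.5 CPM and 99.8% at 2 CPM on the true side, but only 12.7% at 0.9 CPM and 6.83% at 1.1 CPM, with 0.175% and 0.583% on the wrong side, so most genes near 1 CPM stay undecided. All simulated pairs at a log2 ratio of 0.5 were called and none at 0. Those pairs were set at high levels with a small fixed noise and were not drawn from counts. Their result does not cover pairs of genes with few counts. Coherence recovered 3 of 3 simulated lists.

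Some named genes share at least 95% identity over 50% or more of their longest transcript with another annotated gene, by blastn, and their counts are uncertain to that extent. They are Eef1a1, Ldha, Ldhb, Pkm, Odc1, Pcna, Phgdh, Hspd1, Hspa1a, Hspb1, H2afz, Trbc2, Il22, Ifit3, Lyz2, Rn7sk, Rpph1, Gm24187, Gm23935, Gm42418, Gm42047, Trav14n-3, Trav4-4-dv10, Trav14d-3-dv8 and several mitochondrially encoded mRNAs. Alternatives covered the pseudocount, the filter on low values, scaling, the threshold, TPM, thinning every library to the smallest total, DESeq2, the sex chromosomes and leaving out each replicate. The text files that only list other files were not used. No label gives a batch or date, so no batch could be tested.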

Results

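RNA was sequenced from primary T cells of C57BL/6NJ mice, a substrain of the common laboratory mouse. The labels give 1 group of 4 biological replicates and no treatment, so the questions were which genes the cells expressed, at what relative levels, and how the replicates differed. Names inside the file headers add Th0, activated and 48 hours, which the labels do not state. Th0 is the usual name for CD4 T cells stimulated without added polarising cytokines. Counts assigned to genes totalled 56904311 in replicate 1, 45110199 in replicate 2, 127755788 in replicate 3 and 53379135 in replicate 4, a 2.83-fold range. A count of 0 allowed levels of up to 0.053, 0.067, 0.023 and 0.056 CPM (counts scaled to library size) in these libraries, taking 3 counts as the limit. Such floors and all intervals cover counting error only. Each library counted as 1 sample because the labels call it a biological replicate. Every pair differed beyond counting noise, with a chi-square per degree of freedom of 8.30 to 26.3, a test that cannot show the samples to be independent. The labels give the same donor identifier to all 4 replicates, and p-values measure only the spread between these samples.

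The 20 protein-coding genes with the highest TPM (CPM corrected for gene length), leaving out ribosomal protein and mitochondrially encoded ones, had varied functions. Among them the translation elongation factor genes Eef2 and Eef1a1 reached 6427 CPM ± 142 and 5286 ± 224 (mean ± SD, n = 4). The cytoskeletal actin gene Actb stood at 5891 CPM ± 276 and the beta-tubulin gene Tubb5 at 2069 CPM ± 41.6. The translation factor gene Eif5a reached 1884 CPM ± 87.1 and the nucleolar gene Npm1 1903 ± 50.02. Odc1, the first enzyme of polyamine synthesis, stood at 1246 CPM ± 14.6, and the cytokine gene Mif at 395 CPM ± 32.3. The costimulatory receptor gene Tnfrsf4 and the cytokine gene Il2 were also among these 20, at 2395 TPM ± 82.04 and 2008 TPM ± 97.5. Of 23365 genes with a count in any library, 11081 lay above 1 CPM and 11285 below it by limma's one-sided tests on log2(CPM + 0.1), each adjusted over all genes, and 999 passed neither. Of those above, 10453 were protein-coding and 106 were lincRNA genes, and together the genes above 1 CPM held 99.8% of the counts.

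Genes of the T cell receptor complex and its proximal signalling were all expressed. All 18 members of the T cell identity list lay above 1 CPM (18 adjusted over the list alone), with a median of 303.5 CPM. Trac, the constant gene of the receptor alpha chain (ENSMUSG00000076928.5, chromosome 14, 54220521 to 54224206, mm10), stood at 414 CPM ± 10.2 (SD, n = 4), and Trbc2, a beta chain constant gene, at 221 CPM ± 11.5. The receptor regulator gene Cd5 reached 892 CPM ± 34.1 and the CD45-associated protein gene Ptprcap 337 ± 19.4. Cd4, the class II coreceptor gene (ENSMUSG00000023274.14, chromosome 6, 124864692 to 124888221), averaged 792 TPM ± 15.01, while the class I coreceptor genes Cd8a and Cd8b1 averaged 0.263 TPM ± 0.133 and 22.3 TPM ± 1.62. The log2 ratio of Cd4 over Cd8a was 11.15 ± 0.48, adjusted p = 8.86e-07, and that of Cd4 over Cd8b1 5.15 ± 0.13, adjusted p = 4.84e-07 (limma, n = 4). Cd4 was higher in 4 of 4 libraries in both pairs. Of the 13 members of the CD8 and cytotoxic list, 7 lay above 1 CPM (7 adjusted over the list alone), 5 below, and Gzmk had no count. The death ligand gene Fasl led these at 31.6 CPM ± 3.75, the chemokine gene Ccl5 stood at 5.47 CPM ± 0.809 and the granule gene Nkg7 at 2.47 CPM ± 0.191. At a threshold of 2 CPM 4 of the 13 members passed. No member of the gamma-delta T cell list lay above 1 CPM by limma (0 adjusted over the list alone, 1 at an unadjusted p below 0.05); without replicate 2 the count was 1. The delta chain constant gene Trdc stood at 0.397 CPM ± 0.145, and Trac exceeded it by a log2 ratio of 11.75 ± 0.40, adjusted p = 5.56e-07. Trbc2 exceeded the gamma chain constant gene Tcrg-C2 in 4 of 4 libraries (adjusted p = 6.75e-06); as Tcrg-C2 had no count in 3 of them, the pseudocount sets the size of that ratio.

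Genes of activation were expressed at high levels beside most genes of the naive state. All 18 members of the T cell activation list lay above 1 CPM (18 adjusted over the list alone), with a median of 300.2 CPM. The transferrin receptor gene Tfrc reached 1392 CPM ± 30.6 (SD, n = 4), and the receptor genes Tnfrsf4 and Tnfrsf18, whose products costimulate T cells, 952 ± 37.1 and 301 ± 10.99. Nr4a1, an orphan nuclear receptor gene induced by receptor signalling, stood at 725 CPM ± 37.3. The high-affinity interleukin 2 receptor gene Il2ra stood at 555 CPM ± 28.6 and the growth regulator gene Myc at 522 CPM ± 20.9. All 16 members of the naive and quiescent list also lay above 1 CPM (16 adjusted over the list alone), with a median of 142 CPM. Tcf7, a transcription factor gene of naive and memory cells, reached 308 CPM ± 9.71, the lymph node homing receptor gene Ccr7 269 ± 13.3, the antiproliferative gene Btg1 219.6 ± 4.67 and Dapl1 47.3 ± 6.1. Within that list Klf2, a quiescence factor gene, was low at 2.39 CPM ± 0.438, and the survival receptor gene Il7r stood at 6.19 CPM ± 1.13.

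The fixed pairs of these genes gave the same order of TPM in every library. Klf2 lay below Myc (log2 ratio -7.20 ± 0.23, adjusted p = 5.56e-07, limma, n = 4), and Il2ra above Il7r (5.65 ± 0.21, adjusted p = 7.66e-07). Tcf7 exceeded Prdm1, the gene of the effector regulator Blimp-1 (adjusted p = 5.72e-07), by a ratio whose size the pseudocount sets, since Prdm1 had 23 counts in all. The log2 ratio of the inhibitor genes Id3 over Id2 was 5.50 ± 0.24, adjusted p = 1.06e-06, and that of Lef1, a partner of Tcf7, over Id2 was 2.06 ± 0.17, adjusted p = 1.21e-05. Ccr7 exceeded Cd44 in TPM (1.43 ± 0.10, adjusted p = 1.21e-05), but without length correction the log2 ratio was -0.35 (adjusted p = 0.0031). The repressor gene Bach2 lay below the activator protein gene Batf in TPM (-1.08 ± 0.10, adjusted p = 3.54e-05), but at 2.29 without length correction (adjusted p = 1.83e-06). Bcl2 lay below Bcl2l1, the other main survival gene, by -4.29 ± 0.13, adjusted p = 6.48e-07, and Myc above its paralog Mycn by 9.36 ± 0.65, adjusted p = 3.94e-06. In all, 38 of the 40 fixed pairs passed the test, 29 with the first gene higher and 9 with the second. An exact sign-flip test with 4 libraries cannot give a two-sided p below 0.125.

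Regulators of helper T cell lineages were expressed at unequal levels. Gata3, the Th2 factor gene (ENSMUSG00000015619.10, chromosome 2, 9857078 to 9890034), averaged 41.2 CPM ± 2.91 (SD, n = 4), Tbx21, the Th1 factor gene, 3.41 ± 0.527 and Foxp3, the regulatory T cell factor gene, 1.49 ± 0.468. In TPM Tbx21 lay below Gata3 (log2 ratio -2.90 ± 0.22, adjusted p = 7.21e-06, limma, n = 4) and above Foxp3 (1.84 ± 0.43, adjusted p = 0.000434), and Gata3 above Foxp3 (4.74 ± 0.46, adjusted p = 1.21e-05). Foxp3 passed neither test of 1 CPM with all 4 libraries at the chosen settings, but lay above without replicate 3 (1.70 CPM, adjusted p = 0.00351). It also passed with a pseudocount of 0.01 (adjusted p = 0.0169), with an expression filter (0.00689), after rescaling to nuclear protein-coding genes (0.0206) and after thinning (0.0309). Bcl6, the follicular helper factor gene, exceeded its antagonist Prdm1 in 4 of 4 libraries (adjusted p = 4.66e-06), again by a ratio whose size depends on the pseudocount. Zbtb7b, the CD4 lineage factor gene, exceeded Runx3, a CD8 lineage factor gene, by only 0.25 ± 0.12, adjusted p = 0.0169; without replicate 1 the adjusted p was 0.0538 and without replicate 4 it was 0.0718.

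Each helper lineage list was expressed in part, and the effector cytokine genes Ifng, Il4, Il5, Il17a, Il21 and Il22 lay below 1 CPM. Of 13 Th1 members, 8 lay above 1 CPM (8 adjusted over the list alone) and 4 below, with Runx3 at 110.4 CPM ± 8.41 (SD, n = 4), the signal transducer gene Stat4 at 97.7 CPM ± 2.1, the chemokine receptor gene Cxcr3 at 3.68 CPM ± 0.58 and the cytokine gene Ifng at 0.245 CPM ± 0.137. Of 12 Th2 members, 6 lay above (6 adjusted over the list alone), 5 below and Il24 had no count. The chemokine receptor genes Ccr4 and Ccr8 stood at 64.5 CPM ± 4.15 and 42.2 ± 1.71, the repressor gene Gfi1 at 84.1 CPM ± 3.77, and the cytokine genes Il13, Il4 and Il5 at 6.99 CPM ± 0.917, 0.458 ± 0.124 and 0.116 ± 0.0587. Of 14 Th17 members, 6 lay above (6 adjusted over the list alone) and 8 below. The chemokine receptor gene Ccr6 reached 102 CPM ± 9.03 and the aryl hydrocarbon receptor gene Ahr 27.3 ± 0.317, against 0.237 CPM ± 0.05 for Il17a, 0.0137 ± 0.0274 for Il22 and 0.00664 ± 0.00887 for the receptor gene Il23r. Of 15 regulatory members, 12 lay above (13 adjusted over the list alone), 2 below and Foxp3 undecided. The inhibitory receptor gene Ctla4 reached 441 CPM ± 21.4, the helios gene Ikzf2 16.5 ± 0.763 and Ebi3, a cytokine subunit gene, 85.7 ± 4.38, while Itgae and Il10 lay below at 0.276 CPM ± 0.152 and 0.0551 ± 0.0714. Of 11 follicular helper members, 8 lay above (8 adjusted over the list alone) and 3 below, with the receptor genes Btla and Pdcd1 at 352 CPM ± 10.2 and 299.6 ± 9.41, and Il21, Ascl2 and Tox2 below at 0.0375 CPM ± 0.0318, 0.077 ± 0.0592 and 0.139 ± 0.188.

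**Figure D1:**
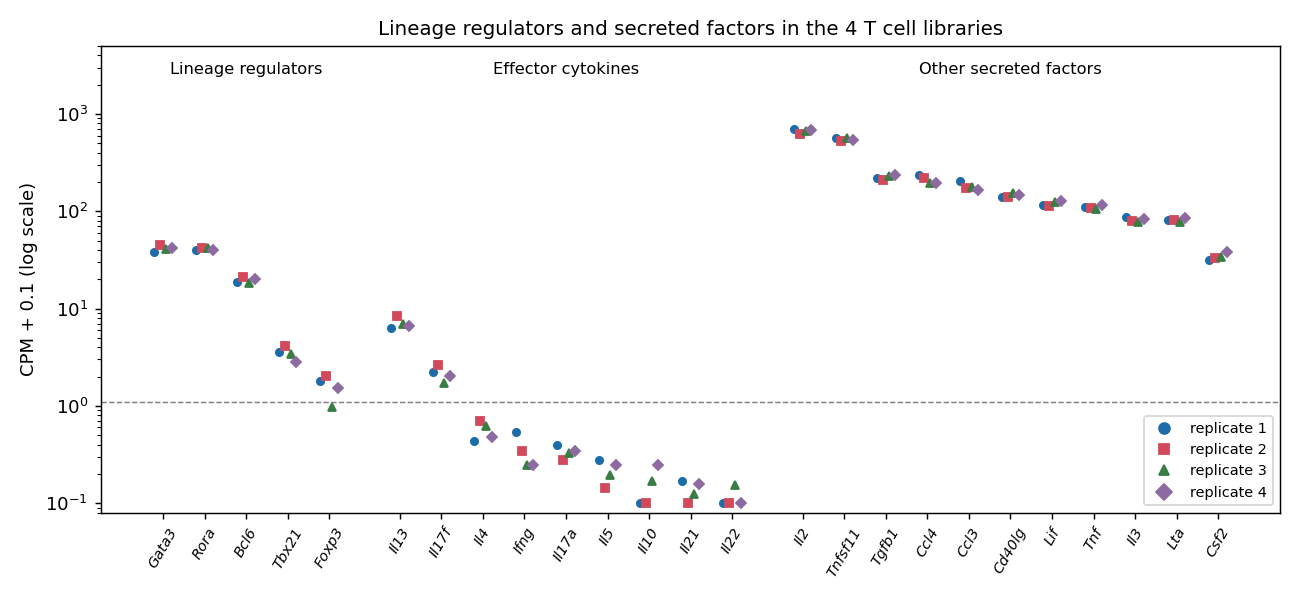
CPM + 0.1 on a log axis for lineage factor and cytokine genes, 1 point per library, with a dashed line at 1 CPM. Gata3 averages 41.2 CPM and Foxp3 1.49 CPM, and Il2 averages 669 CPM and Ifng 0.245 CPM.

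Interleukin 2 led the secreted factors. Il2, the gene of this T cell growth factor (ENSMUSG00000027720.7, chromosome 3, 37120523 to 37125959), reached 669 CPM ± 33.3 (SD, n = 4), and Tnfsf11, which encodes the ligand RANKL, 549 ± 20.2. The chemokine genes Ccl4 and Ccl3 stood at 212 CPM ± 20.4 and 180.1 ± 17.2. The B cell helper ligand gene Cd40lg reached 146 CPM ± 7.34, the myeloid growth factor genes Il3 and Csf2 81.8 ± 4.37 and 34.05 ± 2.61, and the cytokine genes Lif, Tnf and Lta 120.3 ± 7.26, 110.2 ± 4.97 and 81.3 ± 2.85. Of the 31 members of the list, 19 lay above 1 CPM (19 adjusted over the list alone), 10 below, 1 was undecided and Il24 had no count. Il2 exceeded Ifng by a log2 ratio of 11.50 ± 0.62, adjusted p = 1.64e-06 (limma, n = 4). Il4 lay below Il13 (-3.88 ± 0.22, adjusted p = 2.8e-06) and Il17a below its relative Il17f (-2.17 ± 0.44, adjusted p = 0.000252). Il17a and Ifng were not told apart (log2 ratio 0.18 ± 0.58, adjusted p = 0.508). The ratio of Il17a over Il4 was -0.78 ± 0.63, adjusted p = 0.0395, and its adjusted p rose to 0.0925, 0.133 and 0.0718 without replicate 2, 3 or 4. The ratio of Ifng over Il4 was -0.96 ± 0.86, adjusted p = 0.0533; without replicate 1 it was -1.37 (adjusted p = 0.00101), and with a pseudocount of 1 it was -0.48 (adjusted p = 0.0404). On the TPM scale Il4, Il17a, Ifng and Il9 were no longer below the threshold of 1 (adjusted p = 0.224, 0.105, 0.102 and 0.0904).

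Integrin, inhibitory receptor and cytokine receptor genes were widely expressed. The integrin genes Itgal and Itgb2, whose products pair as LFA-1, stood at 1062 CPM ± 32.1 and 309 ± 5.59 (SD, n = 4), and Itgb1 at 347 CPM ± 10.6. Of 26 chemokine receptor and homing genes, 18 lay above 1 CPM (18 adjusted over the list alone), 7 below and Ccr3 had no count. The inhibitory receptor list had 8 of 11 members above (8 adjusted over the list alone), led by the immunoglobulin family gene Cd200 at 541 CPM ± 24.4. Its 3 members below were Cd244a, Entpd1 and Havcr2, at 0.442 CPM ± 0.123, 0.423 ± 0.201 and 0.259 ± 0.152; the first 2 were chosen after their values were seen. Of 25 cytokine receptor and STAT genes, 24 lay above (25 adjusted over the list alone). Il2rg and Il2rb, which complete the interleukin 2 receptor with Il2ra, stood at 345 CPM ± 3.77 and 307 ± 13.7, and Stat6, which transduces interleukin 4 signals, at 426 CPM ± 9.24. Stat3 exceeded Stat4 by a log2 ratio of 0.65 ± 0.05, adjusted p = 0.000126 and Stat5a exceeded Stat5b by 0.48 ± 0.04, adjusted p = 0.000325 (limma, n = 4).

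Cell cycle genes were expressed in all libraries. All 20 S phase genes lay above 1 CPM (20 adjusted over the list alone), with a median of 244 CPM, and all 20 G2 and mitosis genes (20 adjusted over the list alone), with a median of 181 CPM. The replicative helicase genes Mcm3 and Mcm5 reached 657 CPM ± 4.99 and 639.8 ± 11.8 (SD, n = 4), Rrm2, a subunit gene of ribonucleotide reductase, 452 ± 6.53 and the sliding clamp gene Pcna 386 ± 21.7. Top2a, which encodes a topoisomerase of dividing cells, stood at 853 CPM ± 32.8, the cyclin gene Ccna2 at 326 CPM ± 16.4, the anaphase activator gene Cdc20 at 275 CPM ± 8.35 and the mitotic kinase gene Plk1 at 206 CPM ± 11.7. The cyclin D gene Ccnd2 exceeded Ccnd3 by a log2 ratio of 1.16 ± 0.04, adjusted p = 9.96e-06 (limma, n = 4).

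Genes of glycolysis had a higher median than those of oxidative phosphorylation in CPM, which does not correct for gene length (329 and 137 CPM). That order describes these lists and was not tested. Whether it holds with length correction was not tested either. All 20 members of each list lay above 1 CPM, and 20 of each adjusted over the list alone. Ldha, which encodes the lactate dehydrogenase subunit favouring lactate formation, reached 3732 CPM ± 76.7 (SD, n = 4) and exceeded Ldhb by a log2 ratio of 5.83 ± 0.03, adjusted p = 7.2e-08 (limma). Pkm, Gapdh and Aldoa, genes of glycolytic enzymes, reached 2900.0 CPM ± 24.3, 2375 ± 56.8 and 1750.0 ± 54.5. The glucose transporter gene Slc2a1 exceeded Slc2a3 (2.75 ± 0.07, adjusted p = 8.86e-07). The hexokinase gene Hk2 exceeded Hk1 in TPM (0.54 ± 0.08, adjusted p = 0.000434) but not without length correction (0.03, adjusted p = 0.659). The ATP synthase genes Atp5b and Atp5a1 stood at 2186 CPM ± 38.6 and 1478 ± 43.5, Cyc1, a gene of the cytochrome bc1 complex, at 245 CPM ± 9.5 and the cytochrome oxidase gene Cox4i1 at 238 CPM ± 16.6. Of 13 mitochondrially encoded mRNAs, 7 lay above 1 CPM (7 adjusted over the list alone), among them mt-Co1 at 2374 CPM ± 56.1 and mt-Cytb at 954 CPM ± 65.2. The other 6, chosen after their values were seen, were at most 0.0166 CPM (mt-Atp6), and mt-Co2, mt-Atp8 and mt-Nd4l had no count. Of these 6, all but mt-Atp8 have a transcript of at least 99% identity from another annotated gene, and how the counting treated reads that map to both is not given in the sources used here.

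Sterol and serine synthesis genes were expressed throughout. All 15 sterol synthesis genes lay above 1 CPM (15 adjusted over the list alone), with a median of 181 CPM. Srebf2, the master regulator gene of the pathway, reached 853 CPM ± 50.4 (SD, n = 4), and the enzyme genes Hmgcs1 and Cyp51 473 ± 23.1 and 486 ± 13.2. All 13 ATF4 and serine one-carbon genes lay above 1 CPM (13 adjusted over the list alone), with a median of 126 CPM. The stress factor gene Atf4 stood at 544 CPM ± 5.26, the serine pathway genes Phgdh and Shmt2 at 368 CPM ± 15.7 and 616 ± 23.9, and the amino acid transporter gene Slc7a5 at 532 CPM ± 33.2. All 17 immediate early genes lay above 1 CPM (17 adjusted over the list alone), with a median of 64.4 CPM, led by Nr4a1 and the AP-1 subunit genes Junb and Jund at 707 CPM ± 34.7 and 444 ± 10.6.

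Markers of cell types other than T cells were mostly below 1 CPM or without a count. No granulocyte and mast cell marker lay above 1 CPM by limma (8 markers, 0 adjusted over the list alone, 0 at an unadjusted p below 0.05), and S100a8 and S100a9, the abundant granulocyte genes, had no count. No erythroid and platelet marker passed either (9 markers, 0 adjusted over the list alone, 0 at an unadjusted p below 0.05), although Itga2b, undecided at 1.22 CPM ± 0.531 (SD, n = 4), passed without replicate 2 (1.47 CPM, adjusted p = 0.0158). Of 12 macrophage and monocyte markers 2 lay above 1 CPM (2 adjusted over the list alone), Cd68 at 2.69 CPM ± 0.316 and Adgre1 at 2.6 CPM ± 0.332, while the abundant macrophage genes Lyz2, C1qa, C1qb and Tyrobp had no count, nor did Lyz1, a near-identical copy of Lyz2. Cd3e exceeded Lyz2 at least 1306-fold and the haemoglobin gene Hbb-bs at least 762-fold in TPM, taking 3 counts per library as the floor. Its ratio to Ncr1, a natural killer receptor gene with 2 counts in all, had a counting interval of 4010 to 119600. Of 8 natural killer markers 1 lay above (1 adjusted over the list alone), Eomes at 2.34 CPM ± 0.392. Of 8 dendritic cell markers 2 lay above (2 adjusted over the list alone), the class II chaperone gene Cd74 at 108 CPM ± 3.25 and Zbtb46 at 5.76 CPM ± 0.845, while the class II gene H2-Aa stood at 0.31 CPM ± 0.142 and was undecided in TPM (adjusted p = 0.0514). Of 11 B cell markers 2 lay above (1 adjusted over the list alone), the immunoglobulin heavy chain gene Ighm (ENSMUSG00000076617.9, chromosome 12, 113418558 to 113422730) at 161 CPM ± 15.1 and Ebf1 at 1.53 CPM ± 0.471. Ebf1 did not pass without replicate 1, 3 or 4 (adjusted p = 0.148, 0.0586 and 0.0865), which left 1 marker above, and in TPM it lay below 1 (0.538 TPM, adjusted p = 0.0309). Cd79a, which encodes a part of the B cell receptor, and the light chain gene Igkc stood at 0.469 CPM ± 0.103 and 0.353 ± 0.309, and in TPM both were undecided (adjusted p = 0.595 and 0.322). The marker Cd79b was undecided at 0.846 CPM ± 0.36 but lay above 1 in TPM (2.03 TPM ± 0.849). Cd3e exceeded Cd79a by a log2 ratio of 7.58 ± 0.32, adjusted p = 8.86e-07. Of 10 stromal, endothelial and epithelial markers 2 lay above (2 adjusted over the list alone), the adhesion gene Pecam1 at 26.9 CPM ± 1.51 and Epcam at 1.47 CPM ± 0.336. Epcam did not pass without replicate 1, 2 or 4 (adjusted p = 0.0557, 0.087 and 0.0536), which left 1 marker above. Of 7 thymocyte markers Cd8b1 alone lay above (1 adjusted over the list alone), and the recombinase genes Rag1 and Rag2 had no count.

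Histone genes and several small noncoding RNAs, which lack a poly(A) tail, had low counts. Protein-coding genes took 98.7% ± 0.0769 of the counts (SD, n = 4) and lincRNA genes 0.487% ± 0.0711. The 68 replication-dependent histone genes took 0.00345% ± 0.00019, although S phase genes were abundant, and annotated ribosomal RNA genes 0.00019% ± 0.00007. The 2 mitochondrial ribosomal RNA genes took more, 0.0332% ± 0.00199, and Gm42418, whose synonym ties it to 18S ribosomal RNA, stood at 2049 CPM ± 513. Gm42418 is annotated as a lincRNA gene, so its counts fall in the lincRNA share and not in that of annotated ribosomal RNA genes. Ribosomal protein genes took 4.76% ± 0.228, the mitochondrial chromosome 0.608% ± 0.0155, the 10 most abundant genes 4.09% ± 0.0445 and the 100 most abundant 15.4% ± 0.058. In TPM the histone share was 0.018%, the mitochondrial 1.62% and the ribosomal protein 10.5%. Of 16 noncoding RNA genes, 11 lay above 1 CPM (11 adjusted over the list alone), led by the small nucleolar RNA hosts Gas5 and Snhg1 at 255 CPM ± 9.24 and 124 ± 6.75. After rescaling to nuclear protein-coding genes no member of this list is tested, by construction. Among its RNAs without a poly(A) tail, the RNase P RNA gene Rpph1 stood at 2.01 CPM ± 0.16 (21.6 TPM ± 1.76) and Rn7sk, which regulates transcription elongation, at 1.2 CPM ± 0.291. The telomerase RNA gene Terc stood at 0.241 CPM ± 0.162. With length correction Rn7sk lay above 1 (12.5 TPM ± 3.00, adjusted p = 2.98e-07) and Terc was undecided (1.96 TPM ± 1.31, adjusted p = 0.242).

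Many receptor segments were in use. Of 35 beta chain variable segments 27 had a count, and the effective number, the exponential of Shannon entropy, was 15.6 ± 0.44 (SD, n = 4). Trbv31 took 12.5% ± 0.514 of the Trbv counts, Trbv13-2 11.4% ± 0.584, Trbv1 10.2% ± 0.604, Trbv3 8.78% ± 0.901 and Trbv13-1 8.51% ± 0.503. In TPM Trbv13-2 ranked first at 13.4%. In replicate 2, the shallowest library, Trbv31 took 13.2% of 8055 counts (95% Wilson interval 12.4 to 13.9%). Of 128 alpha chain variable segments 81 had a count, with an effective number of 47.6 ± 0.736. By their means Trav14n-3 took 5.27% ± 0.499 of the Trav counts and Trav4-4-dv10 4.91% ± 0.887, but in replicate 1 Trav4-4-dv10 led at 5.76%. Both have near-identical copies among the other Trav segments, so their shares and the effective number are uncertain.

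**Figure D2:**
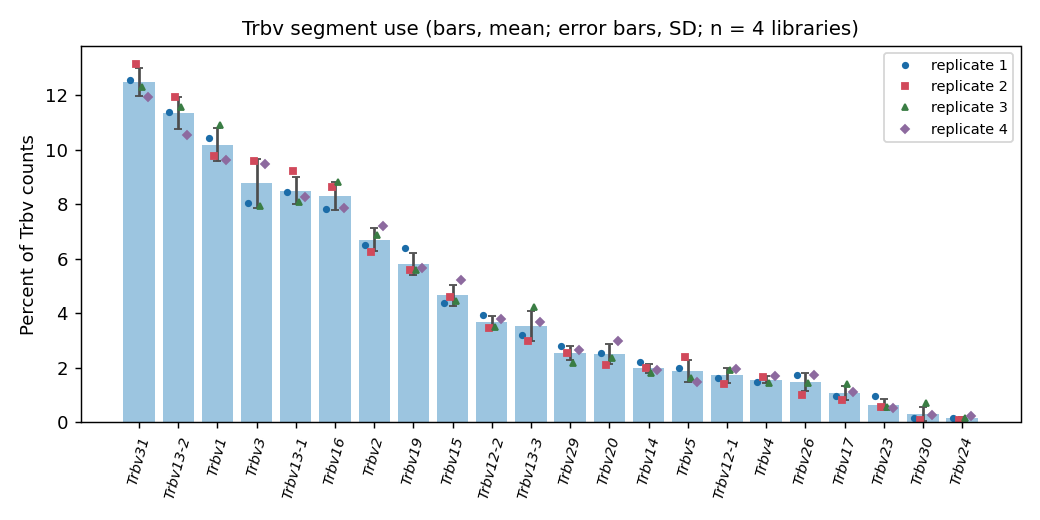
Share of Trbv counts in percent for each beta chain variable segment, with bars at the mean of 4 libraries, error bars of 1 SD and 1 point per library. The top segment, Trbv31, averages 12.5%.

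Sex-linked genes split the replicates 2 against 2. Xist, the RNA that silences 1 X chromosome in female cells (ENSMUSG00000086503.3, chromosome X, 103460375 to 103483217), stood at 708, 763, 0.853 and 1.95 CPM in replicates 1 to 4. The Y chromosome gene Ddx3y stood at 0.176, 0.554, 67.5 and 70.7 CPM in the same order, Eif2s3y at 0.123, 0.399, 56.6 and 60.3 CPM, Kdm5d at 0.141, 0.155, 51.8 and 49.4 CPM and Uty at 0.0703, 0.0443, 33.7 and 33.98 CPM. With all 4 libraries 1 of the 6 sex-linked genes, Xist, lay above 1 CPM (1 adjusted over the list alone), against 5 without replicate 1 or without replicate 2 and 0 in TPM. In the split of replicates 1 and 2 from 3 and 4, which is not a grouping of the study, 10 genes differed by edgeR's quasi-likelihood test, 9 higher in replicates 1 and 2 and 1 lower. Xist differed by a log2 value of 9.25 (SE 0.159, adjusted p = 7.45e-16). The others on the X chromosome were Kdm6a, a histone demethylase gene that escapes silencing, at 0.81 (SE 0.058, adjusted p = 1.26e-06), the escape genes Eif2s3x and Kdm5c at 0.74 and 0.49, Pbdc1 at 0.71, 5530601H04Rik at 0.68 and Mid1 at 1.77. Ddx3x, the X chromosome partner of Ddx3y, did not differ by this test (0.03, adjusted p = 0.894). Off the X, the opioid precursor gene Penk was higher by 0.52, the signalling regulator gene Rgs10 by 0.44, and Gm43305 lower, at -1.30. Mid1 was not called by DESeq2 (adjusted p = 0.779), and thinning to the smallest total ended the calls of Mid1, Rgs10 and 5530601H04Rik (adjusted p = 0.0505, 0.0505 and 0.107). The filter on low counts left 1 Y chromosome gene in the test; with the minimum asked of 2 libraries 16 genes differed, with no filter 59 and by DESeq2 23. Without the X and Y chromosomes 2 genes differed and Rgs10 was lost (adjusted p = 0.0568).

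**Figure D3:**
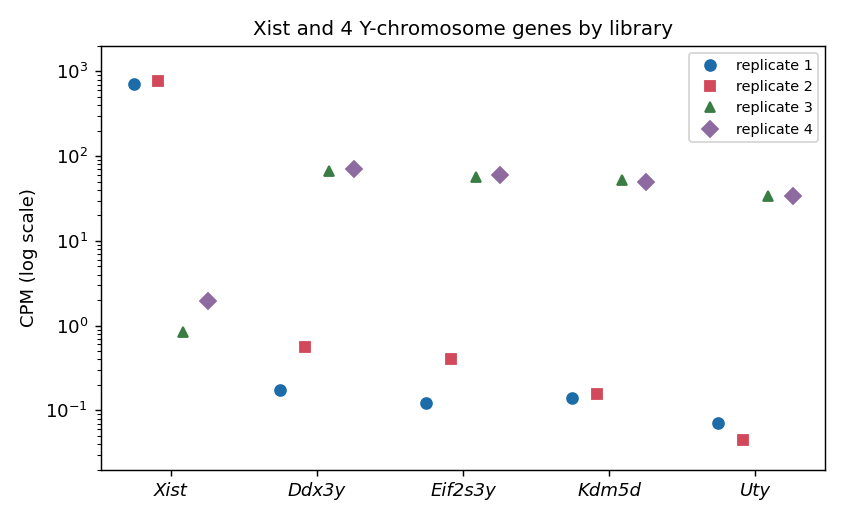
CPM on a log axis for Xist and 4 Y chromosome genes in each of the 4 libraries, 1 point per library. Xist lies at 708 and 763 CPM in replicates 1 and 2 and at 0.853 and 1.95 CPM in replicates 3 and 4.

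A different split, of replicates 1 and 3 from 2 and 4, separated a group of genes on chromosome 4. Alpl, the tissue-nonspecific alkaline phosphatase gene (ENSMUSG00000028766.10, chromosome 4, 137741733 to 137796384, mm10), stood at 4.83, 22.6, 5.81 and 29.4 CPM in replicates 1 to 4, a log2 difference of -2.28 (SE 0.141, adjusted p = 7.61e-10, edgeR). Its neighbour Ece1, the endothelin-converting enzyme gene (ENSMUSG00000057530.14, chromosome 4, 137862237 to 137965229), stood at 138, 222, 144 and 220.5 CPM, a difference of -0.65 (SE 0.062, adjusted p = 1.41e-06). Ubxn11 (ENSMUSG00000012126.16, chromosome 4, 134102570 to 134127593) and the nucleosome-binding protein gene Hmgn2 (ENSMUSG00000003038.15, chromosome 4, 133964738 to 133968650) differed by -0.77 and 0.33. Bin2, a membrane-shaping protein gene on chromosome 15 (ENSMUSG00000098112.7, chromosome 15, 100641077 to 100669553), stood at 98.9, 183, 106 and 185 CPM, a difference of -0.85 (SE 0.054, adjusted p = 7.61e-10). The exchanger gene Slc9a9 and Gm42047 were higher in replicates 1 and 3, by 1.65 and 0.57, and the ribosomal protein gene Rps29 lower, at -0.38. In all 8 genes differed, 3 higher and 5 lower in replicates 1 and 3. With no filter on low counts 24 differed, and with the minimum asked of 2 libraries 5, when Hmgn2, Ubxn11, Gm42047 and Rps29 were lost (adjusted p = 0.111, 0.0892, 0.385 and 0.0761). Thinning also ended the calls of Hmgn2 and Gm42047 (adjusted p = 0.11 and 0.0862), and DESeq2 that of Gm42047 (adjusted p = 1). In the remaining split, of replicates 1 and 4 from 2 and 3, edgeR called 0 genes, with 612 at an unadjusted p below 0.05, and DESeq2 called 5; with no filter the count was 22 and without the X and Y chromosomes 7.

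**Figure D4:**
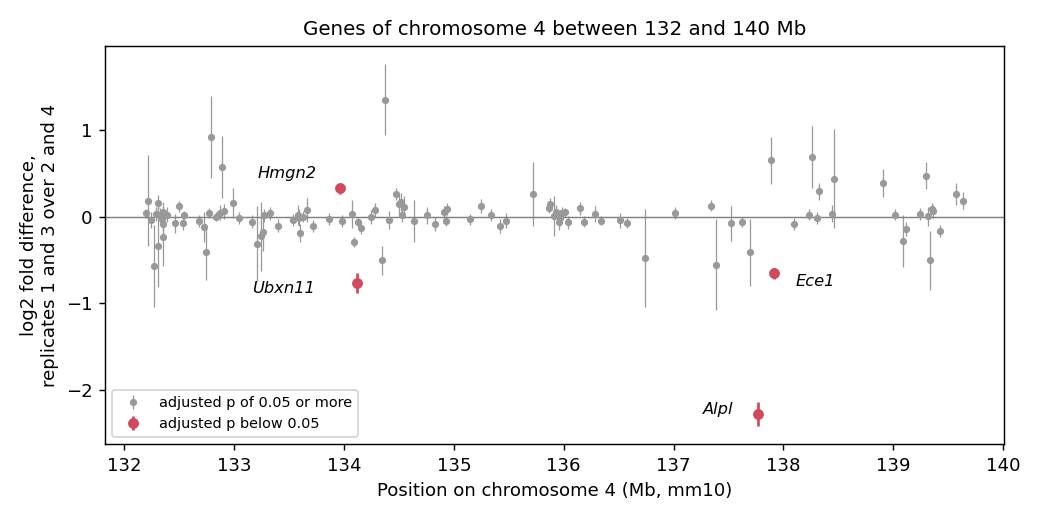
Log2 difference of replicates 1 and 3 over 2 and 4 for the genes around Alpl and Ece1 on chromosome 4, with error bars of 1 SE and genes past the threshold in red. Alpl lies at -2.28 and Ece1 at -0.65.

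Single libraries stood apart in few genes. In replicate 1, 9 genes were lower than in the other 3 libraries and 0 higher by edgeR's quasi-likelihood test. The noncoding genes Gm42418 and Gm26917, next to each other on chromosome 17, stood at 1308, 2383, 2403 and 2102 CPM and at 499, 1063, 928 and 888 CPM in replicates 1 to 4, differences of -0.82 (SE 0.052, adjusted p = 1.05e-06) and -0.95 (SE 0.072, adjusted p = 6.29e-06). Gm42418 carries the synonym Rn18s-rs5, a name for sequence related to 18S ribosomal RNA. The mitochondrial leucyl-tRNA synthetase gene Lars2 stood at 539.8, 1069, 874 and 833 CPM, a difference of -0.78 (adjusted p = 0.0013), and was lost by DESeq2 (adjusted p = 0.0578). Across the libraries Lars2 ran in the same order as Gm26917. Whether differing amounts of residual ribosomal RNA reads lay behind both was not tested. The others were Gm15564, Mir6236, Gm24187, Gm42031, Gm23935 and the cytolinker gene Plec, the last at -0.36. Gm42031 was lost without replicate 3 (adjusted p = 0.0602). Of the 9 genes DESeq2 called 5, and besides Lars2 it did not call Gm15564, Mir6236 and Gm42031. In replicate 3 the gene Cdk5rap1, which encodes a tRNA-modifying enzyme, was lower by a log2 value of -1.19 (SE 0.159, adjusted p = 0.0178), a call lost without replicate 1 (adjusted p = 0.0682) and not made by DESeq2. EdgeR called 0 genes in replicates 2 and 4, with 1055 and 261 at an unadjusted p below 0.05, and DESeq2 called 8 and 1. These counts moved with the libraries compared. Without replicate 2, replicate 1 alone had high Xist, against replicates 3 and 4 with high Y chromosome genes. The same held for replicate 2 without replicate 1. In those fits a deviation of the library cannot be told apart from the split in sex-linked genes. For replicate 1 the count was 525, 18 and 91 without replicates 2, 3 and 4. For replicate 2 it was 272, 34 and 47 without replicates 1, 3 and 4, for replicate 3 it was 5, 4 and 17 without replicates 1, 2 and 4, and for replicate 4 it was 21, 20 and 10 without replicates 1, 2 and 3. With no filter on low counts 123, 100, 28 and 25 genes were called in replicates 1 to 4, and DESeq2 called 37 in replicate 1 and 6 in replicate 3.

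Few genes varied between the libraries beyond the trend of genes of their abundance. By edgeR's goodness-of-fit test 56 of 13279 genes did so, led by Xist, Mid1 and Alpl. Mid1, a ubiquitin ligase gene at the pseudoautosomal boundary of the mouse X, stood at 22.8, 40.5, 12.8 and 4.85 CPM in replicates 1 to 4. The count was 33, 40, 37 and 37 without replicates 1, 2, 3 and 4, of which 26, 32, 37 and 34 were among the 56. By the quasi-likelihood dispersion test it was 25, all among the 56, and by goodness of fit with the minimum asked of 2 libraries 73. The filter on low counts left 1 Y chromosome gene in the test, so Ddx3y, Eif2s3y, Kdm5d and Uty were not among the genes tested. The biological coefficient of variation was 7.64% and the median SD of log2 CPM was 0.0895.

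Members of 7 of the 27 lists with at least 5 tested members varied together between libraries more than 10000 random lists of matched size and abundance (one-sided permutation test). By permutation they were nuclear oxidative phosphorylation (p = 1e-04, the smallest these draws can give, adjusted p = 0.0027), ATF4 and serine one-carbon (adjusted p = 0.0027), immediate early (adjusted p = 0.0027), p53 targets (adjusted p = 0.00472), Th2 (adjusted p = 0.0184), cytokine receptors and STATs (adjusted p = 0.0238) and mitochondrially encoded mRNA (adjusted p = 0.0312). Mean log2 deviations over the 4 libraries ran from -0.13 to 0.19 in the Th2 list, from -0.15 to 0.11 in the p53 list, from -0.12 to 0.10 in the ATF4 list, from -0.09 to 0.07 in the immediate early list and from -0.07 to 0.07 in the oxidative phosphorylation list. In the mitochondrial list they ran from -0.05 to 0.08 and in the cytokine receptor list from -0.03 to 0.06. Genes are not independent replicates, so this describes these libraries. By the same permutation test, without replicate 1 the oxidative phosphorylation, ATF4 and cytokine receptor lists were lost (adjusted p = 0.111, 0.145 and 0.334), and without replicate 2 the Th2, cytokine receptor and p53 lists (adjusted p = 0.631, 0.177 and 0.963), when 4 lists passed. Without replicate 3 the mitochondrial list was lost (adjusted p = 0.0597), and without replicate 4 the Th2 and mitochondrial lists (adjusted p = 0.0618 and 0.697). The immediate early list passed in each of these fits. The inhibitory receptor list passed without replicate 1 or 3 (adjusted p = 0.0304 and 0.0423), and the naive and homing lists without replicate 3 or 4 (adjusted p from 0.0275 to 0.0494).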

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

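The test of whether 1 library stood apart from the other 3 was fixed before the data were examined, and no explanation was tested for these values. Of 267 values tested in the 4 libraries, 14 had a library far from the others, where chance gives about 1 in 20, or 13.3. They fell 6 times on replicate 1, 3 times on replicate 2, 5 times on replicate 3 and 0 times on replicate 4.

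Replicate 1 stood above the others in Tnfrsf18 (317 CPM against 293.1 to 297.1) and Cd8a (0.4921 CPM against 0.1957 to 0.2217). It stood below them in Slc2a3 (57.83 CPM against 63.11 to 63.91) and Entpd1 (0.123 CPM against 0.5058 to 0.5542). Its share of Trav counts in Trav14d-3-dv8 was low, at 3.299% against 4.271 to 4.343%. Its mean log2 deviation in the CD8 and cytotoxic list was high, at 0.18 against -0.083 to -0.047.

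Replicate 2 stood below the others in Id3 (379.4 CPM against 444.7 to 451.4) and in the sterol synthesis list (mean log2 deviation -0.024 against 0.006 to 0.011), and above them in Il2rg (350.6 CPM against 342.8 to 343.5). Replicate 3 stood above the others in Cd4 (945.2 CPM against 924.4 to 927.4) and in total counts (127755788). It alone had counts in Ncr1 (0.01565 CPM), Il22 (0.05479 CPM) and Tcrg-C2 (0.07827 CPM), where a count of 0 in the other libraries allowed up to 0.067 CPM.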

How the results depend on the processing

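The TPM, thinning, 2-library minimum, sex chromosome and DESeq2 split alternatives were chosen after seeing the data; the others were fixed earlier. Of 86 counts and shares recomputed under other settings 58 stayed about the same (counts within 1.5 times, shares within 1 SD), and of 80 recomputed without 1 replicate 64 did. Leaving out 1 of 4 libraries cannot move a mean share, or a mean effective number of segments, by 1 SD. Those 64 therefore include every share and effective number by construction, and only the gene, pair and list counts could change. Of 2822 results for single genes, pairs and lists under other settings 2710 kept their direction and side of the threshold, and 1426 of 1507 did without 1 replicate. These results also hold shares of further segments and gene classes, which again could not change without 1 replicate. The number of genes above 1 CPM was the same by this measure under every alternative.

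The number below 1 CPM, 11285, followed by construction the genes tested: 38547 with no filter on low values, 1183 with filterByExpr and 4037 with nuclear protein-coding genes only. Epcam, at 1.471 CPM, lay above the threshold of 1 and below a threshold of 2. Correction for gene length turned Ebf1, at 0.5382 TPM, to below the threshold, and without it Ccr7/Cd44 (log2 ratio -0.3456, reported as 1.43) and Bach2/Batf (2.295, reported as -1.08) turned. The log2 ratio of Il17a/Ifng, undecided at 0.18, ran from -0.003088 to 0.3584 without 1 replicate, and the cause was not tested.

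The 56 variable genes became 25 by the quasi-likelihood dispersion test and 33 to 40 without 1 replicate. Genes deviating in replicates 1, 2, 3 and 4 numbered 9, 0, 1 and 0. They became 123, 100, 28 and 25 with no filter on low counts and 37, 8, 6 and 1 by DESeq2. Without 1 of the other replicates they ran from 18 to 525, 34 to 272, 4 to 17 and 10 to 21. The split of replicates 1 and 2 against 3 and 4, with 10 genes, gave 59 with no filter, 16 with the minimum in 2 libraries, 2 without chromosomes X and Y and 23 by DESeq2. That of 1 and 3 against 2 and 4, with 8, gave 24 with no filter and 5 with the minimum in 2 libraries. That of 1 and 4 against 2 and 3, with 0, gave 22 with no filter, 7 without chromosomes X and Y and 5 by DESeq2. Splits were not rerun without 1 replicate. The 7 coherent lists became 4 to 9 without 1 replicate. The cause was not tested for any change in this paragraph. The highest counts for replicates 1 and 2, without replicates 2 and 1 respectively, came from comparisons that followed the split in Xist and Y chromosome genes.

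In TPM, which by construction weights short genes more, Trbv31 took 11.96% of the Trbv total (12.5% of counts), mitochondrial genes 1.616% (0.608%), ribosomal protein genes 10.48% (4.76%), histone genes 0.01799% (0.00345%), protein-coding genes 94.86% (98.7%), the top 10 genes 7.389% (4.09%) and the top 100 genes 22.41% (15.4%).

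Posterior mean TPM and credible interval bounds were not run, since the files analysed hold no such columns. No paired analysis was possible because the labels give 1 group only. Depth limits genes near 0 counts: the smallest library allows up to 0.067 CPM at a count of 0.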

Other observations

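Stress and interferon genes were expressed to different degrees. All 10 p53 target genes lay above 1 CPM by limma (10 adjusted over the list alone), with a median of 117 CPM. Ccng1, which encodes cyclin G1, reached 580.3 CPM ± 43.01 (SD, n = 4), the cell cycle inhibitor gene Cdkn1a 391 ± 17.3, the apoptosis gene Bax 189.5 ± 10.6 and Phlda3 96.6 ± 2.19. Of 11 hypoxia genes, 10 lay above (10 adjusted over the list alone), among them Hif1a, the oxygen-regulated factor gene, at 226 CPM ± 10.4 and Pdk1, which restrains pyruvate entry into mitochondria, at 141 CPM ± 1.73. Car9, the undecided member, was chosen after its value was seen and stood at 1.01 CPM ± 0.35. Chaperone genes of the heat shock list were abundant, with Hsp90ab1 at 5489 CPM ± 98.6, Hspa8 at 1769 CPM ± 67.5 and the mitochondrial chaperone gene Hspd1 at 1154 CPM ± 14.9. The heat-inducible genes Hspa1a and Hspb1, chosen after their values were seen, lay below 1 CPM at 0.471 CPM ± 0.014 and 0.169 ± 0.166, but in TPM Hspb1 was undecided (0.562 TPM, adjusted p = 0.0999). In all 8 of 11 heat shock genes lay above (8 adjusted over the list alone).

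Of 17 interferon response genes, 11 lay above 1 CPM (11 adjusted over the list alone) and 5 below. The antiviral membrane protein gene Bst2 stood at 73.4 CPM ± 2.01 (SD, n = 4), Ifi27l2a at 67.3 CPM ± 3.42, and the GTPase genes Igtp and Gbp2 at 37.1 CPM ± 3.78 and 21.8 ± 2.43. The 5 below, chosen after their values were seen, were Ifit3, Mx1, Rsad2, Oasl2 and Rtp4, of which Ifit3 stood highest at 0.539 CPM ± 0.0559; in TPM it was undecided (1.06 TPM, adjusted p = 0.682).

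The tests on sex-linked genes, linked sequence differences, the S phase median and RNAs without a poly(A) tail were chosen after the result was seen. No biological explanation was tested as a contrast, since the labels give 1 group.

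Xist was high in replicates 1 and 2 and the Y chromosome genes in replicates 3 and 4, while the labels give 1 donor identifier and no sex. Libraries from 1 animal, or from animals of 1 sex, are argued against by the lowest ratio of the second to the third highest library among these 5 genes, 122. Loss of Xist RNA in otherwise like animals is argued against by the Y genes, whose lowest level in the libraries with low Xist was 33.7 CPM. Source animals of both sexes are a candidate explanation: of the 9 other genes of that split, 6 lie on the X, all higher in replicates 1 and 2, against 3.3% of tested genes (exact hypergeometric p = 9.62e-08). The low Y gene levels in replicates 1 and 2, 0.131 to 0.802% of the mean in replicates 3 and 4, stay open.

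Alpl, Ece1, Ubxn11 and Hmgn2 lie within 5 Mb on chromosome 4 and separated replicates 1 and 3 from 2 and 4, a different split, though Hmgn2 and Ubxn11 were lost with the minimum asked of 2 libraries (adjusted p = 0.111 and 0.0892). After thinning to the smallest total the median log2 difference of these 4 genes was 1.01 times its value, with 3 of 4 past the threshold. Those 3 calls therefore did not need the extra counts of the deeper libraries. Thinning leaves the expected ratio between libraries unchanged, so it cannot decide whether depth lay behind the differences. Replicates 1 and 3 had totals of 56904311 and 127755788 counts, against 45110199 and 53379135 in replicates 2 and 4, so depth stays open. Cells of another type in replicates 2 and 4 are argued against by the summed markers of 8 types, which rose by at most 7.87 CPM (B cell) against 80.4 CPM for Ece1. A copy number difference across the whole interval is argued against by the 51 other tested genes of the interval, whose median log2 difference was 0.013 (interquartile range 0.147), while one limited to the adjacent Alpl and Ece1 stays open. Linked sequence differences between the source animals are a candidate explanation that these counts cannot decide. Of those 51 genes 5, or 9.8%, had an unadjusted p below 0.05 against 3.1% of all tested genes (exact hypergeometric p = 0.0196). The interval was bounded by genes called in the same split, and its genes, such as Cd52 beside Ubxn11, are not independent of them. Bin2, Slc9a9, Gm42047 and Rps29, also called in this split, lie on other chromosomes. Other local changes could give this pattern too, and no sequence was examined.

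Histone genes and 6 other RNAs without a poly(A) tail had low counts although the labels name total RNA. Cells that were not dividing are argued against by the S phase list, whose median was 244 CPM. Reads shared between near-identical histone genes are argued against only in part by the 22 such genes with no near-identical transcript, whose median was 0.356 CPM. Identity was scored over each gene's own longest transcript, so some of the 22 still hold shared sequence. Hist1h4j, for example, was matched by Hist1h4k at 98.4% identity over 100% of the Hist1h4k transcript. Hist1h1t, Hist1h2ba and Hist1h2aa, also among the 22, had no count. Selection of RNA with a poly(A) tail is a candidate explanation: of 6 RNAs without a tail the highest, Rpph1, averaged 2.01 CPM (21.6 TPM), while the polyadenylated histone genes H2afz, H3f3a and H3f3b averaged 298 CPM ± 18.7, 61.6 CPM ± 5.46 and 586 CPM ± 30.2 (SD, n = 4; 575, 60.3 and 676 TPM). Rpph1 and Rn7sk, but not Terc, have near-identical transcripts of other genes. Reads shared with those could also lower the counts of Rpph1 and Rn7sk, which was not tested. Gm42418, tied by its synonym to 18S ribosomal RNA, at 2049 CPM ± 513, goes against complete selection. Size selection and depletion steps, which could also lower short RNAs, were not tested.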
